A study of Mus musculus with 4 samples.

How the data were processed

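Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on mouse spermatocytes, the meiotic cells of the testis. Per the labels' protocols, testis cells of C57BL/6 animals carrying a LAP-tagged Smc1b construct were fixed with formaldehyde and sorted for green fluorescence. The series holds 4 libraries. One was precipitated with an antibody against SMC3, one with an antibody against GFP, which recognises the tag on SMC1B, and each has its own input library. Values were analysed for the 2 ChIP libraries. The inputs were not analysed here. Each target is represented by 1 library, so nothing below has a replicate check, and the tests describe these lists, singly or against each other, rather than replicated conditions.

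The submitters' processing notes name Bowtie2 0.12.8, MACS2 and the mouse assembly mm9. How the input was used, how duplicate and multiply mapped reads were treated, and the cutoff of the initial peak call are not given in the sources used here. Each deposited file is a list of 1-base peak summits with a score, which the authors' peak caller gave as the −log10 of the q-value of the peak. That reading of the column was checked on the values, since the lowest score of each list lies just above the −log10 of its false discovery rate (FDR). For SMC3 the deposited lists use an FDR of 0.001 and of 0.1. For SMC1B-LAP they use an FDR of 0.1 and of 0.5. The lists carry the running numbers of a longer call, which reach 94678 for SMC3 and 1510666 for SMC1B-LAP, so the deposited summits are the part of that call that passed the stated FDR. A score depends on depth and on the list it comes from. Within one list it was used to rank or classify summits and to compare medians. Between the lists, scores were correlated over pairs of summits. The read depth behind the summits is unknown, because the lists hold no counts.

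Both targets were compared on their FDR 0.1 lists, the threshold they share. Coordinates are given as 1-based mm9 positions. No gene annotation of mm9 was used, so the planned promoter, gene list and gene density comparisons were not run and no genes are assigned to summits. The gene table at hand describes a later assembly, and on 10 of 21 chromosomes the last summit lies beyond the last gene of that table. The mitochondrial summit of each list was left out of tests, which leaves 19 autosomes, X and Y.

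Summits of the 2 targets were called shared within 500 bp. The shared share was compared with 999 circular shifts, in which all SMC1B-LAP summits of a chromosome were moved by one random offset within the extent from the first to the last summit. The p-values are two-sided and cannot go below 0.001. Mutual nearest pairs within 500 bp were used for distances and for correlations of scores, tested with 100000 permutations. Summits per chromosome were set against the chromosome's share of the summed extent with two-sided exact binomial tests, adjusted by Benjamini-Hochberg over 42 tests. Chromosome shares were compared between targets with Fisher's exact test, adjusted over 21 chromosomes. These tests treat summits as independent, and clustered summits make their p-values too small. The X to autosome ratio divides summits per Mb of extent. The share in the first and the last of 10 equal parts of each autosome was tested with an exact two-sided sign-flip permutation over 19 autosomes, adjusted over 4 tests. Windows of 100 kb on a fixed grid were called densely filled where the Poisson upper tail, with the chromosome's mean, passed 0.05 after Bonferroni correction. The spacing of neighbouring summits was compared with 999 sets of uniform random positions. Intervals of shares are exact (Clopper-Pearson) 95% intervals and cover the counting error of summits only.

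The regions to be named were fixed before the data were examined. They are the 10 highest-scoring summits of each target, the 5 fullest 100 kb windows of each target, the 10 mutual pairs with the best sum of ranks, and chromosomes that passed adjusted p 0.05 by over 1.2 times. The chromosome 17 cluster, the X region and the 50 bp distance were chosen after values were seen. Planned score deciles were replaced by fixed score classes, because 4899 of 10685 SMC1B-LAP summits share one score. Alternatives covered distances of 100 bp to 5000 bp, the other FDR lists, local shifts of 10 to 100 kb, removal of densely filled windows, 1 summit per 10 kb, autosomes only, and windows of 10 kb and 1 Mb. The density of running numbers on X was also computed, after the ratio among mutual pairs had left chance stacks on X undecided, and is given as a value only, since X is present once in male cells and coverage was not measured. Leaving out SMC1B-LAP summits at the tied score and leaving out densely filled 1 Mb windows were added after seeing the data.

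The procedures were tested on simulated data, in 40 sets with 12% of SMC1B-LAP summits planted at SMC3 summits and 40 sets without. The mean share recovered above the shifts was 11.9%, and 40 of 40 planted sets reached p of 0.05 or lower against 1 of 40 unplanted sets. A planted X to autosome ratio of 1.5 was recovered as 1.48. No window was called densely filled in the unplanted sets (0 over all of them). Apart from the planted summits, simulated positions were drawn uniformly over each chromosome, which is what the window test assumes. The sets therefore do not show how the tests behave on clustered summits such as those of the real lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.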

Results

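Binding of 2 cohesin subunits was mapped in mouse spermatocytes. Cohesin is the ring-shaped complex that holds sister chromatids together and organises chromosome axes in meiosis. SMC3 is a core subunit of every cohesin complex, and SMC1B is the meiosis-specific partner that replaces SMC1A in part of them. SMC1B carried an N-terminal LAP tag, a localization and affinity purification tag containing GFP. The FDR 0.1 lists held 17778 summits for SMC3 and 10685 for SMC1B-LAP. The stricter SMC3 list, at an FDR of 0.001, held 7315 summits, all of which were in its FDR 0.1 list. The looser SMC1B-LAP list, at an FDR of 0.5, held 40801 summits and contained all 10685. Scores reached 116 for SMC3 and 85.2 for SMC1B-LAP, with medians of 2.62 and 1.07 in the FDR 0.1 lists. With 1 library per target there are no replicates, and the read depth is unknown.

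The first comparison asks how far the 2 subunits occupied the same sites. Of 10684 SMC1B-LAP summits on the nuclear chromosomes, 1537 lay within 500 bp of an SMC3 summit, a share of 14.4% (95% interval 13.7% to 15.1%). Circular shifts gave a mean of 0.707% and at most 1.07%, so the observed share was 20.4 times that of shifted positions (circular permutation p = 0.001, the smallest the shifts can give). In the other direction, 1517 of 17777 SMC3 summits had an SMC1B-LAP summit within 500 bp, or 8.53% (8.13% to 8.95%) against 0.423% in the shifts. Coincidence was close: 1149 of the 1483 mutual nearest pairs were within 50 bp, 33 pairs had the identical base, and the median distance was 14 bp. At 50 bp the share of SMC1B-LAP summits with an SMC3 neighbour was 10.8% against 0.0714% in the shifts, 151 times as many. Local shifts of 10 to 100 kb, which keep the regional density, gave a mean of 1.20% at 500 bp. The SMC1B-LAP list at FDR 0.5 gave a share of 6.81%, 9.88 times its shifts, and the SMC3 list at FDR 0.001 gave 10.3%, 34.5 times its shifts. The share of SMC3 summits with an SMC1B-LAP neighbour was 15.2% and 14.7% with these lists. The shifts address chance coincidence only. Artefacts common to both libraries were not excluded here or for the shared sites below, since the inputs were not analysed.

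**Figure D1:**
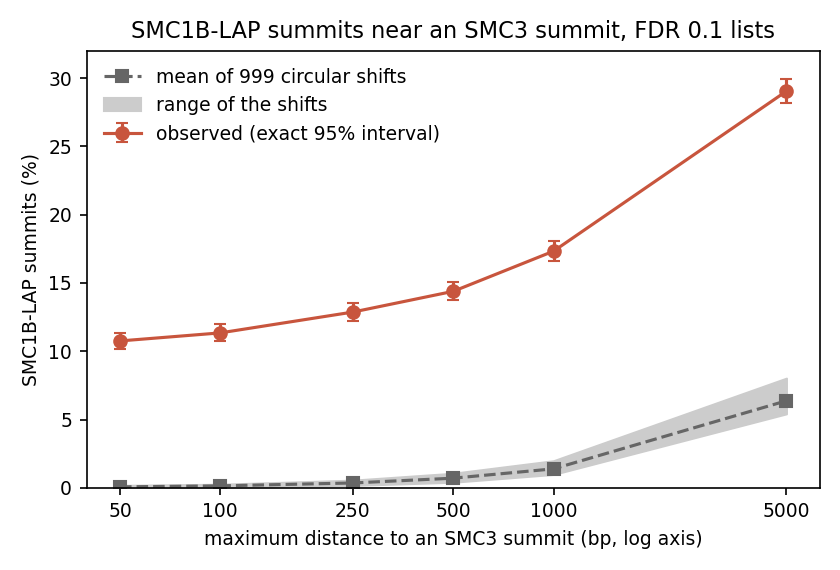
Share of SMC1B-LAP summits (y axis, percent of 10684) with an SMC3 summit within the distance on the x axis (bp, log axis). Red points show the observed share with exact 95% intervals, grey squares the mean of circular shifts and the band their range; the observed share is 10.8% at 50 bp and 29.0% at 5000 bp, where the shifts average 6.37%.

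Shared summits had higher median scores than the rest, although many summits with low scores were shared too. Of the 1537 shared SMC1B-LAP summits, 532 had scores of 1 to 1.5. Of the 1400 SMC3 summits with scores of 10 or more, 516 had a partner. SMC3 summits near SMC1B-LAP had a median score of 5.79 against 2.40 for the rest, and SMC1B-LAP summits near SMC3 had 1.86 against 1.07 (circular permutation p = 0.001 for each). Within 1000 bp the difference of medians for SMC3 was 1.95 instead of 3.39. Among SMC1B-LAP summits with scores of 10 or more, 116 of 151 had an SMC3 partner, 76.8% (69.3% to 83.3%). In the lowest class, scores of 1 to 1.5, the share was 8.41% (7.73% to 9.12%), against 0.699% in the shifts. For SMC3 the corresponding shares were 36.9% (34.3% to 39.4%) and 3.17% (2.69% to 3.71%). Across the 1483 pairs the 2 scores were related with Pearson's r = 0.33 and Spearman's rho = 0.31 (p = 1e-05 for both in the permutation test, the smallest it can give). These correlations are across sites of 2 libraries, and sites are not independent replicates.

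**Figure D2:**
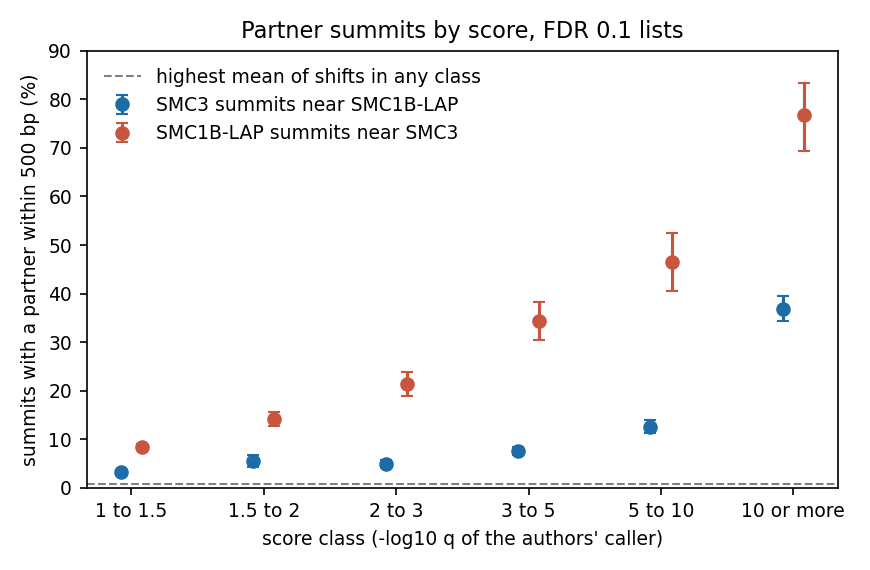
Share of summits with a summit of the other target within 500 bp (y axis, percent) by score class (x axis, −log10 q as the authors' caller gave it), with exact 95% intervals, SMC3 in blue and SMC1B-LAP in red. The share rises from 8.41% to 76.8% for SMC1B-LAP and from 3.17% to 36.9% for SMC3; the dashed line marks the highest mean of circular shifts in any class.

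All 10 highest-scoring SMC3 summits had an SMC1B-LAP summit at 0 to 27 bp, and all 10 highest-scoring SMC1B-LAP summits had an SMC3 summit at 1 to 36 bp. Of the 1000 highest of each target, 434 SMC3 and 442 SMC1B-LAP summits had such a partner within 500 bp. The SMC3 summits lay on chromosome 13 at 92.81 and 69.86 Mb, chromosome 5 at 15.34 Mb, chromosome 4 at 34.50 and 32.61 Mb, chromosome 12 at 18.35 and 49.93 Mb, chromosome 8 at 94.71 Mb, chromosome 9 at 40.86 Mb and chromosome 10 at 93.55 Mb. Their scores ran from 88.4 to 116. The SMC1B-LAP summits, with scores from 51.1 to 85.2, lay on chromosome 14 at 104.74 Mb, chromosome 17 at 56.34 and 4.63 Mb, chromosome 6 at 132.41 Mb, chromosome 1 at 12.63 and 45.01 Mb, chromosome 7 at 105.21 Mb, chromosome 12 at 49.93 Mb, chromosome 9 at 19.38 Mb and chromosome 2 at 60.24 Mb. Only the chromosome 12 site at 49.93 Mb was among the 10 highest of both targets. There the SMC3 summit at position 49931870 scored 88.4 and the SMC1B-LAP summit at 49931869 scored 57.6. The ranks of the partners differed widely at other sites. The highest SMC3 summit, at position 92813940 of chromosome 13, had an SMC1B-LAP partner with a score of 1.79, which ranked 3516 in its list. The highest SMC1B-LAP summit, at position 104736210 of chromosome 14, had an SMC3 partner with a score of 6.89, which ranked 2353. By the sum of both ranks the leading pairs were those on chromosome 5 at 15337549, chromosome 12 at 49931870, chromosome 8 at 94708832, chromosome 10 at 93550551 and chromosome 9 at 102030268, all positions of the SMC3 summit. They were followed by chromosome 6 at 132413780, chromosome 18 at 59546272, chromosome 4 at 99867404, chromosome 17 at 4626292 and chromosome 2 at 149350365. In these 10 pairs the summits were 1 to 44 bp apart.

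The second comparison asks how the subunits were distributed over the chromosomes, with the sex chromosomes, each present once in a male cell, as a case of its own. Chromosomes 14, X and Y held more summits than their length predicts and chromosomes 2, 11 and 19 fewer, in both targets (adjusted p below 0.05, exact binomial test), and no other chromosome passed in the FDR 0.1 lists. Without densely filled windows 5 chromosomes passed for SMC3, X no longer among them, and 8 for SMC1B-LAP, with chromosomes 3 at 1.10 and 9 at 0.831 added. In the other lists 6 passed for SMC3, with chromosome 15 at 0.850 in place of 14, and 8 for SMC1B-LAP, without X and with chromosomes 6, 7 and 13 added. Chromosome 2, at 0.892 for SMC3 and 0.836 for SMC1B-LAP, departed by less than the 1.2 times set for naming and is given because its values were seen. On X, SMC3 had 8.64 summits per Mb against 6.74 on the autosomes, a ratio of 1.28 (1.21 to 1.35, exact binomial p = 5.93e-18). SMC1B-LAP had 6.43 per Mb against 3.94, a ratio of 1.63 (1.53 to 1.74, exact binomial p = 5.04e-45). On the assembled part of Y the ratio was 4.43 (3.55 to 5.48, exact binomial p = 1.25e-28) for SMC3, from 86 summits, and 9.87 (8.12 to 11.9, p = 1.53e-69) for SMC1B-LAP, from 112. Keeping 1 summit per 10 kb lowered the Y ratios to 2.94 and 4.76, and the SMC1B-LAP list at FDR 0.5 gave 4.50. The SMC1B-LAP ratio on Y was 5.65 without densely filled 1 Mb windows and 15.6 without the summits at the tied score. Chromosome 19 was lowest, at 0.807 of expectation (0.722 to 0.898) for SMC3 and 0.729 (0.626 to 0.844) for SMC1B-LAP. Chromosome 11 stood at 0.816 (0.756 to 0.879) and 0.764 (0.690 to 0.844), and chromosome 14 at 1.14 (1.07 to 1.21) and 1.20 (1.11 to 1.30).

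**Figure D3:**
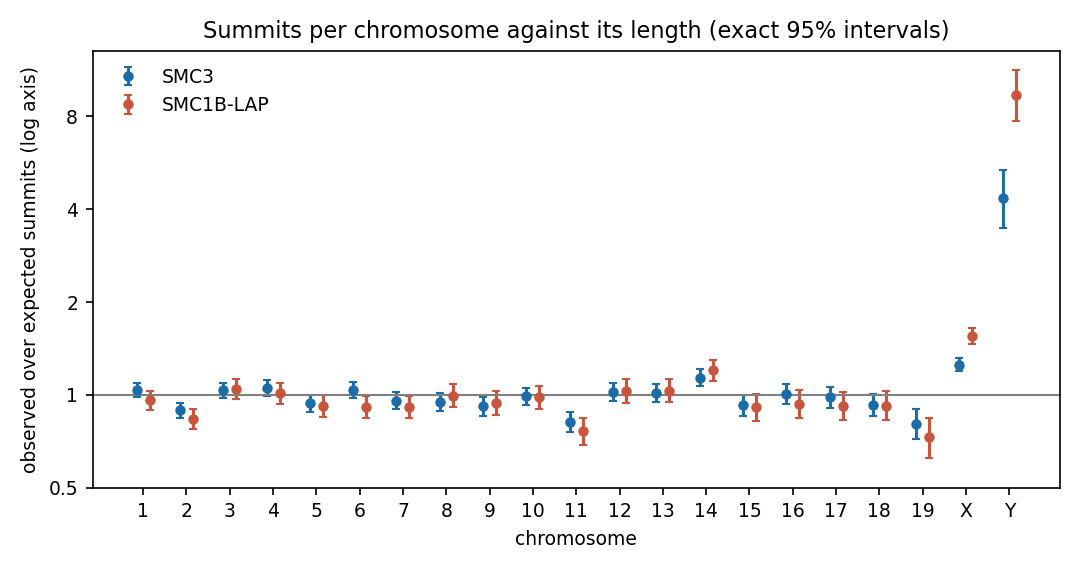
Observed over expected number of summits (y axis, log axis) for each chromosome (x axis), where the expected number follows the chromosome's extent; points carry exact 95% intervals, SMC3 in blue and SMC1B-LAP in red. Y stands at 4.34 for SMC3 and 9.41 for SMC1B-LAP, and X at 1.25 and 1.55; the autosomes lie between 0.729 and 1.20.

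The 2 targets differed in their share of summits on X and Y and on no autosome. X held 9.83% of SMC1B-LAP and 7.94% of SMC3 summits (odds ratio 1.26, 95% interval 1.16 to 1.37, adjusted p = 6.04e-07, Fisher's exact test). Y held 1.05% and 0.484% (odds ratio 2.18, 1.63 to 2.92, adjusted p = 6.04e-07, Fisher's exact test). On chromosome 6, the nearest to the threshold among the autosomes, the odds ratio was 0.878 (0.789 to 0.977, adjusted Fisher's exact p = 0.118). Both differences depended on the SMC1B-LAP list. With that list at FDR 0.5 the X to autosome ratio of SMC1B-LAP was 0.999 (0.959 to 1.04). SMC3 stayed at FDR 0.1, so the thresholds were then unlike. In that comparison the odds ratio of X against autosomes, SMC1B-LAP over SMC3, was 0.779 (0.728 to 0.834), and that of Y was 1.02 (0.785 to 1.32). Under the other alternatives the odds ratio of X stayed above 1, at 1.18 (1.06 to 1.31) with SMC3 at FDR 0.001. It was 1.27 and 1.28 without densely filled 100 kb and 1 Mb windows, 1.29 with 1 summit per 10 kb and 1.58 without the tied SMC1B-LAP summits. Without the tied SMC1B-LAP summits the odds ratio of Y was 3.52 (2.59 to 4.78). It fell to 1.62 (1.07 to 2.43) with 1 summit per 10 kb. Removing densely filled windows gave 1.84 (1.32 to 2.57) for 100 kb windows and 1.70 (1.08 to 2.66) for 1 Mb windows.

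A large part of the X summits came from a single region. Between 120.1 and 122.9 Mb of X lay 309 SMC3 summits where the chromosome's mean predicts 24.2, and 238 SMC1B-LAP summits where it predicts 18.0. These were 21.9% and 22.7% of all X summits of the 2 targets. The other densely filled 1 Mb windows of X started at 3, 29, 31, 32 and 53 Mb. Without densely filled 100 kb windows the SMC3 ratio on X was 1.05 (0.988 to 1.12) and that of SMC1B-LAP 1.33 (1.24 to 1.43). Without the 36 densely filled 1 Mb windows of the genome, 8 of them on X, the X to autosome ratio was 0.948 (0.887 to 1.01) for SMC3 and 1.22 (1.13 to 1.31) for SMC1B-LAP.

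**Figure D4:**
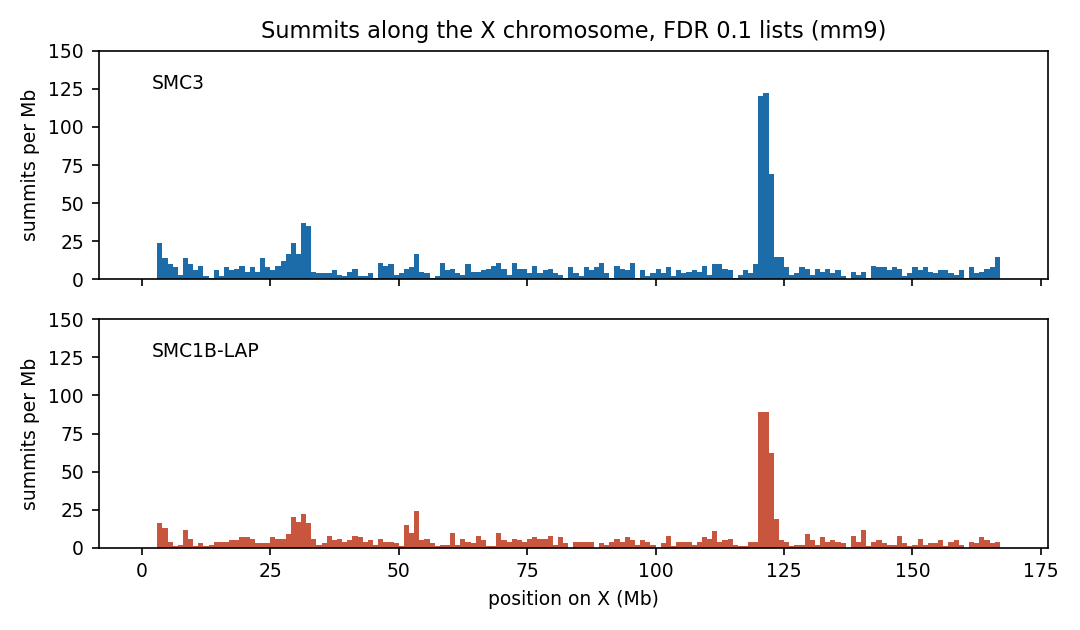
Number of summits per 1 Mb window (y axis) along the X chromosome (x axis, Mb, mm9) for SMC3 (upper, blue) and SMC1B-LAP (lower, red), FDR 0.1 lists. The fullest window of SMC3 starts at 121 Mb and holds 122 summits, and that of SMC1B-LAP starts at 120 Mb and holds 89.

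Clusters of summits were then sought genome-wide, since the series is about accumulation at repeated loci, the ribosomal DNA (rDNA) among them. Of 25818 windows of 100 kb, 43 were densely filled for SMC3 and 32 for SMC1B-LAP, and 20 of them were the same windows. They held 2.95% of SMC3 and 4.13% of SMC1B-LAP summits. The fullest SMC3 windows were those of X starting at 120.1, 120.7, 120.5 and 121.2 Mb, with 23, 22, 21 and 19 summits, and the window of chromosome 5 from 14.9 to 15.0 Mb with 22. For SMC1B-LAP the fullest window was the first of chromosome 9, from 3.0 to 3.1 Mb, with 76 summits where 0.391 were expected. SMC3 had 4 summits there where 0.634 were expected, short of the threshold after correction for the number of windows. The window of Y from 2.8 to 2.9 Mb held 33 SMC1B-LAP and 12 SMC3 summits, and that of chromosome 8 from 72.0 to 72.1 Mb held 21 and 6. On X the windows starting at 121.2 and 120.7 Mb held 26 and 20 SMC1B-LAP summits. The number of densely filled windows for SMC3 was 16 with 10 kb windows and 24 with 1 Mb windows. Neighbouring summits were closer than uniform positions in both targets, with a median spacing of 85538 bp for SMC3 and 137042 bp for SMC1B-LAP. Random sets of uniform positions averaged 99662 and 163390 bp, and the lowest such sets gave 97359 and 158514 bp.

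On chromosome 17 a tight group of summits of both targets, singled out after its values were seen, lay between positions 39983702 and 39984515. The assembly has a stretch resembling the 45S pre-ribosomal RNA unit in this part of the chromosome, which is stated from background knowledge, since no mm9 annotation was used. In these 814 bp lay 4 SMC1B-LAP summits, at 39983702, 39983845, 39984287 and 39984515, with scores of 2.90, 2.36, 4.84 and 1.72. SMC3 had 2 summits there, at 39983705 with a score of 1.23 and at 39984282 with a score of 4.49, each 3 to 5 bp from an SMC1B-LAP summit. In the order of these positions, 10.8%, 16.9%, 4.11% and 34.2% of all SMC1B-LAP summits scored as high or higher. For the 2 SMC3 summits these shares were 97.6% and 24.7% of all SMC3 summits, so the SMC3 summit at 39983705 stood near the low end of its list. Only 5 stretches of the genome held as many SMC1B-LAP summits within this length, 3 of them in the first window of chromosome 9, 1 on chromosome 15 at 74916010 to 74916803, and this one. Both the length and the count were taken from this group, so the small number does not measure its rarity. For SMC3, 490 summits began a stretch of this length with at least 2 SMC3 summits. The 100 kb window around the group held 5 SMC1B-LAP and 3 SMC3 summits and was not densely filled. Most rDNA repeats lie outside the assembled chromosomes, so their coverage cannot be read from these lists.

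The last comparison concerns position along the chromosome. Mouse autosomes have their centromere at one end, where the coordinates start. The first 10% of the extent of the autosomes held 13.4% ± 5.35 (SD over 19 autosomes) of SMC1B-LAP summits, and was above 10% on 15 of 19 autosomes (exact sign-flip permutation p = 0.00391, adjusted 0.0156). With the SMC1B-LAP list at FDR 0.5 the share was 11.5% and no longer passed (adjusted exact permutation p = 0.174). For SMC3 it held 11.5% ± 3.28 and exceeded 10% on 12 of 19 (exact permutation p = 0.0627, adjusted 0.107). Whether the targets differed here was not tested. The last 10% held 9.73% ± 2.29 of SMC3 and 8.84% ± 2.72 of SMC1B-LAP summits, and neither passed the test (adjusted exact permutation p = 0.625 and 0.107).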

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

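The tests on score classes, on X without the tied score and on the chromosome 9 window were chosen after the result was seen. Differences between the targets were found in the share of summits on X (odds ratio 1.26, SMC1B-LAP over SMC3) and on Y (odds ratio 2.18), both by Fisher's exact test of the difference itself. With the SMC1B-LAP list at FDR 0.5 the odds ratio against autosomes turned to 0.779 (0.728 to 0.834) for X and was 1.02 (0.785 to 1.32) for Y.

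In the excess of summits on X, the first pattern, removing densely filled 100 kb windows lowered the X to autosome ratio of SMC3 from 1.28 (1.21 to 1.35) to 1.05 (0.988 to 1.12), which ended the call because the ratio came close to 1, whereas SMC1B-LAP went from 1.63 to 1.33 (1.24 to 1.43), so in this list repeats collapsed in such windows cannot be the whole cause for SMC1B-LAP. Chance stacks of few reads at the tied score cannot be its whole cause either, since without them the SMC1B-LAP ratio rose to 2.03 (1.87 to 2.20). At scores of 1 to 1.5, the class that holds the tied summits, SMC1B-LAP had an excess on X (1.36, 1.24 to 1.48). SMC3 had none in that class (0.978, 0.866 to 1.10). Chance stacks with higher scores stay open. The ratio among mutual pairs outside densely filled windows was 1.06 (0.841 to 1.31, 88 pairs on X), an interval that includes 1. Its upper end lay just below the SMC1B-LAP ratio of 1.33 outside the same windows, but the 2 intervals overlap. Pairs shared with SMC3 thus showed no clear excess on X, and unshared summits were not tested alone. A lower background estimate on X that raises the scores of weak stacks stays open too: summits of score 10 or more had ratios of 0.899 (0.709 to 1.13, 80 on X) for SMC3 and 0.844 (0.357 to 1.71, 8 on X) for SMC1B-LAP, with intervals that include 1, the ratio was highest at scores of 3 to 5 (1.54 and 2.69), and the SMC1B-LAP excess was absent from the FDR 0.5 list (0.999). For SMC3, repeated sequence and clustered binding within the 120 to 123 Mb region cannot be told apart without input coverage or a repeat annotation. A higher load of SMC1B cohesin on the X axis remains an untested biological possibility. SMC3, a subunit of every cohesin complex, had a ratio of only 1.05 (0.988 to 1.12) outside densely filled windows. The lists thus give no clear sign of more cohesin in total there.

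The second pattern is the 4899 SMC1B-LAP summits, 45.8% of the list, that share the score 1.07. A tie of this size may come from chance stacks of few reads that all reach the same small height. Their share within 500 bp of an SMC3 summit was nonetheless 7.33%, 10.6 times the mean of circular shifts and above the highest shift (1.08%), which argues against chance stacks as the source of the whole class; artefacts shared by both libraries were not excluded. The share was 20.4% for the summits with other scores. How many of the remaining tied summits are chance stacks stays open.

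The third pattern is the group of 76 SMC1B-LAP summits in the first 100 kb of chromosome 9, 0.711% of the list (0.561% to 0.889%). If reads of a collapsed repeat piled up there whatever the antibody, SMC3 should show a like share, but 4 SMC3 summits made up 0.0225% of that list. These 4 were still 6.31 times the expected 0.634 (0.00407 in the Poisson upper tail of this window alone, and 1 after correction for all windows), so a pile-up in both libraries that is weaker in SMC3 stays open. A difference between the 2 libraries or their inputs in how repeat reads were kept could also give the group, as could binding of SMC1B near the centromere, and neither was tested. SMC3 is a subunit of every cohesin complex, so binding of SMC1B cohesin should bring SMC3 summits too, and there were 4. With 1 library per target and unknown read depth this count does not decide the matter.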

How the results depend on the processing

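Leaving out tied SMC1B-LAP scores and leaving out densely filled 1 Mb windows were chosen after seeing the data; the other alternatives were not. Of 122 alternative values for 24 results, 111 kept the direction and the side of the threshold, or a count within 1.5 times. Some of the 111 could not have changed, because the altered list did not enter them. The SMC3 ratios on X and Y with another SMC1B-LAP list are examples. The share and the fold of the same overlap were counted as separate results. Chromosome counts were compared by number only, although X dropped out for SMC3 without densely filled windows. The overlap kept its direction and a circular permutation p of 0.001 under every alternative run, with folds for SMC1B-LAP summits from 4.56 at 5000 bp to 78.5 at 100 bp. With the SMC1B-LAP list at FDR 0.5 the X to autosome ratio of SMC1B-LAP turned to 0.999. The odds ratio of X between targets turned to 0.779 and that of Y to 1.02, with SMC3 kept at FDR 0.1. That SMC1B-LAP list adds summits below the FDR 0.1 score, and the cause was not tested further. The odds ratio of X stayed above 1 under every other alternative run. The SMC3 ratio on X was 1.05 without densely filled 100 kb windows and 0.948 without such 1 Mb windows. On Y, keeping 1 summit per 10 kb gave ratios of 2.94 for SMC3 and 4.76 for SMC1B-LAP. Densely filled windows numbered 22 for SMC3 at FDR 0.001 and 66 for SMC1B-LAP at FDR 0.5, where list size differs by construction, and for SMC3 16 with 10 kb and 24 with 1 Mb windows. The SMC1B-LAP share in the first 10% of the autosomes was 11.5% at FDR 0.5 and no longer passed after adjustment (exact permutation p = 0.174); the cause was not tested. The SMC3 share in the last 10% of the autosomes was 10.1% at FDR 0.001, on the other side of 10% but within its spread. No paired analysis was possible because each target has 1 library, and for the same reason no replicate could be left out. Chromosome lengths of a reference as the denominator, and all promoter, gene list and gene density alternatives, were not run, as no mm9 genome or annotation was used. Read depth is unknown, so an unshared summit is only one not detected in the other target. Whether the site was unbound there, missed at this depth or a false call in its own list cannot be told.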

Other observations

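The correlation between targets, the joining of windows into regions, the score classes on X and the running numbers were chosen after the result was seen, while the removal of densely filled windows was set before its value. The autosomes that carried few or many summits were alike in the 2 targets. Across 19 autosomes the observed over expected summits of SMC3 and SMC1B-LAP were correlated with Pearson's r = 0.90 (permutation p = 1e-05, the smallest possible) and Spearman's rho = 0.74 (permutation p = 0.00054). Without chromosomes 11 and 19, the farthest from the median of SMC3, r was 0.81 (permutation p = 7e-05). Autosomes are not independent replicates. That a few densely filled windows set these densities was tested by removing them, and r was then 0.92 (permutation p = 1e-05). A property of the chromosomes common to both libraries, such as the share of sequence to which reads can be mapped or gene content, may underlie the correlation and was not tested.

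Outside the sex chromosomes, several autosomal regions held densely filled windows of one or both subunits. Their borders were drawn around such windows, so their densities are high by selection. Chromosome 4 from 145.3 to 146.8 Mb held 82 SMC3 and 42 SMC1B-LAP summits, 7.52 and 6.68 times the chromosome's mean. Chromosome 5 from 14.9 to 15.2 Mb held 42 and 25, which is 21.6 and 21.9 times the mean. Chromosome 8 from 19.7 to 20.1 Mb held 44 and 43, at 16.8 and 26.1 times. Chromosome 8 from 71.9 to 72.1 Mb leaned the other way from the list sizes, with 13 SMC3 and 29 SMC1B-LAP summits. Its windows were densely filled for SMC1B-LAP only. Chromosome 6 from 114.4 to 114.6 Mb held 23 SMC3 and 4 SMC1B-LAP summits, with windows densely filled for SMC3 only. Differences between targets within these regions were not tested.

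The X to autosome ratio was highest at scores of 3 to 5 in both targets, and for SMC1B-LAP it was also above 1 in the lowest class. For SMC3 the X to autosome ratio was 0.978 (0.866 to 1.10) for scores of 1 to 1.5, 1.54 (1.37 to 1.72) for scores of 3 to 5 and 0.899 (0.709 to 1.13) for scores of 10 or more. For SMC1B-LAP the same classes had 1.36 (1.24 to 1.48), 2.69 (2.13 to 3.38) and 0.844 (0.357 to 1.71). The median 1 Mb window of X held 6 SMC3 summits, as did the median autosomal window, and 4 SMC1B-LAP summits against 3. In the longer call that the running numbers stand for, X had 0.495 times as many numbered peaks per Mb as the autosomes for SMC3 and 0.304 times for SMC1B-LAP, and Y had 1.97 and 0.534 times.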
